A study of Mus musculus with 6 samples.

How the data were processed

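Mouse liver RNA was sequenced in 6 libraries, 3 SKO and 3 DKO, made with standard Illumina methods after Trizol extraction, per the labels. The deposited files hold the authors' raw read counts, whole numbers for each of 54232 Ensembl genes, with 1 file per library. The submitters' processing notes name cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 and the genome build mm10. The roles and settings of these tools, the annotation release and whether counting used the strand are not given in the sources used here. HTSeq counts reads by gene, and reads that map to several places or to overlapping genes may be dropped or divided between copies, so values of the Ces1, Mup, Sult2a, Cyp and Gst families and of genes that overlap others on either strand carry that uncertainty. Gapdh, which has many pseudogenes, had only 119 to 205 counts per library, so other genes with many pseudogenes, such as those of ribosomal proteins, may be undercounted too. No rows for unassigned reads were in the files, so 0 such rows were removed.

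Samples were grouped by the genotype in the labels. Replicate numbers were given in accession order and name libraries only. The labels tie no library of one group to one of the other. Titles of 4 libraries, 3 DKO and 1 SKO, carry 2 numbers whose meaning is not given. If these were pools of animals, the spread among libraries would be smaller than that among animals, and more so in DKO than in SKO, and the SDs and p-values would carry that. Gene symbols and coordinates were taken from GENCODE M21, an annotation of the same assembly as mm10, in which 54165 of the 54232 identifiers matched and 67 did not. No counts were found in any library for 27528 genes.

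Total counts ranged from 16966422 to 21107674 per library. Libraries of a group were compared in 6 pairs before averaging. Their counts differed by 11.2 to 33.4 in chi-square per degree of freedom, far over sampling noise, so no library appeared to be deposited more than 1 time. Pearson's r of log2 CPM across genes was 0.988 to 0.995 within groups and 0.971 to 0.985 between them, where genes are not independent replicates. Intervals and limits based on counts cover counting error only.

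Counts as deposited were filtered with filterByExpr and tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, glmQLFit and glmQLFTest with robust estimation, DKO against SKO, with 4 residual degrees of freedom before moderation across genes. Adjusted p-values are Benjamini-Hochberg values over the 13986 genes tested, and a gene was called at an adjusted p under 0.05. TMM factors were 0.928, 0.903 and 0.951 in SKO and 1.13, 1.06 and 1.05 in DKO. The median biological coefficient of variation was 0.109. Normalised counts-per-million values (CPM) are counts divided by the library total times its TMM factor. The standard error of a log2 fold change is its size divided by the square root of the F statistic. For genes with at most 3 counts in a group, the ratio of normalised counts is given with its 95% counting interval, or as a lower bound taking 3 counts over the group.

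Before the data were examined, 35 gene lists, the tests, the alternatives and a rule for the genes named were fixed, the lists from general knowledge. They hold 762 symbols, of which 1 was not matched and 3 were matched by an older symbol, and 10 genes are in more than 1 list. The rule names Nr1h4 and Xbp1, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, the 3 called members with the smallest p from each list or, with none called, the 2 with the highest mean CPM, 14 genes of bile acid, UPR, lipid and fibrosis biology whatever their result, and, for the closing section, 8 called genes in no list with at least 10 CPM. Some genes chosen in this way are not reported here. Members of a list were counted as higher, lower or not called in the gene-wise fit, and again with p-values adjusted over the list alone. Lists with at least 5 tested members, 32 in all, were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, with camera with an estimated correlation, and with fry, each adjusted over the 32 lists.

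With the preset correlation camera called 22 lists, and none held with an estimated correlation. When it estimates the correlation, camera also tests on the 4 residual degrees of freedom, so that test is weak here. For the clock list the estimated correlation was 0.00574, below the preset 0.01, and its adjusted p still went from 0.00256 to 0.189. A call lost there thus does not show that correlation between genes made it. The preset p-values are still not taken alone here. In the 9 other splits of the 6 libraries into 3 and 3, camera with the preset correlation called 8 to 21 lists. Fry called 20 lists in the real split and 0 in the others. Each other split keeps part of the genotype difference in its contrast and puts the rest into the residual spread, so these counts do not measure false calls. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes.

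The fit was tested on simulated counts with the means of the SKO libraries and the dispersions and library sizes of the 6 libraries, over 13986 genes. Each gene was drawn independently, and 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, far fewer than were called in the data. Of genes changed 1.5-fold, 2-fold and 4-fold, 49.3%, 70.1% and 86.4% were recovered, and 8 of 145 calls were false. A list raised 1.5-fold was called by camera with the preset correlation and 0 of 39 unchanged lists were. With independent genes this does not measure false calls among lists whose genes move together.

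Alternatives were median-ratio (RLE) and upper-quartile factors, total counts alone, no filter, a minimum of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, and leaving out each library in turn. Tables were handled and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Bootstrap intervals of list medians used 10000 resamples of members. They measure the spread among genes, taken as independent, and not the spread between libraries.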

Results

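Gene expression was measured by RNA sequencing of liver from male C57BL/6 mice fed chow and aged 8 to 10 weeks, in 2 groups of 3 libraries. Mice of both groups lacked FXR, the nuclear bile acid receptor encoded by Nr1h4. The control group, called SKO in the labels, carried floxed Xbp1 alleles, and the other group, called DKO, also lacked Xbp1 in the liver. Xbp1 encodes a transcription factor of the unfolded protein response (UPR), and its mRNA is spliced into the active form by the endoplasmic reticulum (ER) sensor IRE1. The comparison of DKO with SKO asked what loss of hepatic XBP1 changes in FXR-null liver. A wild-type group and a group lacking Xbp1 alone were not analysed here, so every change is relative to SKO. Total counts per library were 16966422, 20211285 and 18681577 in SKO and 21107674, 19320210 and 18382107 in DKO. At these depths 3 counts correspond to between 0.126 and 0.191 in normalised counts-per-million, which is the upper 95% limit that a count of 0 allows, for counting error only. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

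Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893 in mm10) was lower in each DKO library than in any SKO library. Its mean fell from 247 ± 18.9 to 77.1 ± 16.3 in normalised counts-per-million (CPM, mean ± SD, n = 3 per group), a log2 fold change of -1.68 ± 0.14 (SE; edgeR adjusted p = 0.000146). These counts cover the whole gene, and the deleted part of the gene is not given in the sources used here, so reads from undeleted exons and from other cell types may be included. Nr1h4 (ENSMUSG00000047638, chromosome 10, 89454234 to 89533585) was counted at 98.6 ± 5.94 CPM in SKO and 97.4 ± 3.35 CPM in DKO, with a log2 fold change of -0.02 ± 0.07 (edgeR adjusted p = 0.891). Its transcript was thus counted in both groups, and without knowing which exons the FXR-null allele lacks, this value does not check the Nr1h4 genotype. Xist was at most 0.342 CPM in any library and the Y-linked Ddx3y at least 69.5 CPM. Of the 4 Y-linked genes tested, edgeR called Ddx3y lower in DKO (log2 -0.26 ± 0.07, adjusted p = 0.0259), and 3 were lower adjusted over the list alone. That call ended without any library except DKO replicate 3 (edgeR adjusted p up to 0.0746) and with upper-quartile or total-count scaling.

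Of 13986 genes tested, 2803 differed between the groups at an edgeR adjusted p under 0.05, of which 1446 were higher and 1357 lower in DKO. Changes of at least 2-fold were mostly rises, with 573 genes higher and 178 lower. The first principal component of log2 CPM held 63.1% of the variance and separated the groups. DKO replicate 1 lay at 45.7 on it, beyond DKO replicates 2 and 3 at 19.8 and 27.5, while the SKO libraries lay between -36.3 and -27.6. Albumin mRNA took 5.05% to 6.82% of the counts in SKO and 3.33% to 4.35% in DKO, and the 20 most counted genes took 19.7% to 22.1% and 17.1% to 18.3%. Scaling by total counts alone moved the median log2 fold change of all genes from 0.006 to 0.23 and the share of higher calls from 51.6% to 87.8%, and upper-quartile factors gave 65.3%, so small changes below are relative to the median gene. Leaving out SKO replicate 2, SKO replicate 3 or DKO replicate 3 left 1419, 1784 and 1831 genes, and without DKO replicate 1 or SKO replicate 2 the rises of at least 2-fold numbered 363 and 332. Beside the genes named by the rule given with the processing, the following called genes were named after their values were seen: Creb3l3, Hgsnat, Cyp2e1, Cyp1a2, Ergic3, Tapbp, Bloc1s1, Sparc, Galnt10, Scara3, Col6a1, Pdgfrb, Pmp22, Asns, Akr1d1, Amacr, Abcb1a, Slco1a4, Acot1, Krt23, Ahsg, Alb, Apcs, Saa4, Hp, Aldh1a1, Ces2c, Npas2, Atp5o, Ddx3y and C8b. Of these 31, the 8 called in each fit without 1 library were Hgsnat, Cyp2e1, Cyp1a2, Ergic3, Tapbp, Sparc, Asns and Ahsg, and the other 23 lost their call in at least 1 (edgeR adjusted p up to 0.176).

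Most genes tested of the ER protein-folding and export machinery fell in DKO. Among 39 tested members of the list of ER folding and ER-associated degradation, 25 fell and none rose. Erp44, which retains client proteins in the early secretory pathway, fell from 80.5 ± 6.79 to 31.1 ± 3.17 CPM (log2 -1.37 ± 0.09, edgeR adjusted p = 2.11e-05). P4hb, a protein disulfide isomerase, fell from 1518 ± 79.8 to 660.9 ± 44.7 CPM (log2 -1.20 ± 0.10), and Dnajb9, an ER co-chaperone, from 56.3 ± 3.38 to 30.1 ± 1.35 CPM (log2 -0.90 ± 0.08). Hspa5, the major ER chaperone BiP, fell by 0.33 ± 0.10 on the log2 scale (edgeR adjusted p = 0.0443), from 742 ± 28.6 to 589 ± 57.6 CPM. Of 39 genes for translocation into the ER, signal peptide cleavage and N-glycosylation, 22 fell and none rose, among them Magt1 (log2 -0.90 ± 0.07), Rpn1 (log2 -0.85 ± 0.07) and Tram1 (log2 -0.84 ± 0.07). For ER to Golgi transport, 19 of 37 genes fell and none rose, including the tether Uso1 (log2 -0.78 ± 0.09), the coat subunit Sec23b (log2 -0.70 ± 0.08) and the cargo receptor Lman2 (log2 -0.64 ± 0.08). Adjusted over the list alone, 32, 26 and 22 members of these 3 lists were lower, and 1, 0 and 1 higher. Median log2 fold changes were -0.35, -0.38 and -0.28. By camera, which tests a list against all other genes, the adjusted p-values were 1.9e-20, 1.08e-15 and 7.77e-09, but adjusted p = 0.189, 0.14 and 0.243 with an estimated correlation. By fry the adjusted p-values of these lists were 0.00743, 0.00414 and 0.0083. Without SKO replicate 3, 1 folding gene was higher, and without DKO replicate 2 or without a filter 1 transport gene. Under total-count scaling 14, 15 and 8 members were lower and 0, 4 and 5 higher, and the call for Hspa5 ended (log2 -0.11), as it did with upper-quartile factors (log2 -0.27) and, with adjusted p-values up to 0.164 in edgeR, on leaving out any library except DKO replicate 1.

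Most sensors and regulators of the UPR were not called. Among 15 genes tested, 4 fell and none rose: Dnajc3, an inhibitor of the eIF2-alpha kinases (log2 -0.75 ± 0.08), Sil1, a nucleotide exchange factor of BiP (log2 -0.57 ± 0.09), Bfar (log2 -0.34 ± 0.08) and Creb3l3, a liver-enriched ER-bound transcription factor (log2 -0.33 ± 0.08). Creb3l3 lost its call without SKO replicate 2 or DKO replicate 3 and with total counts, and Bfar with total counts. In the fits without SKO replicate 3, without DKO replicate 1 and without a filter, 1 member was higher. With upper-quartile factors 2 were higher and 4 lower. When adjusted over the list alone, 5 were lower and 2 higher. Ern1, which encodes IRE1-alpha, was 101 ± 10.7 CPM in SKO and 121 ± 3.23 CPM in DKO and was not called (log2 0.26 ± 0.09, edgeR adjusted p = 0.0573). The camera adjusted p of the list was 0.0196, with adjusted p = 0.243 with an estimated correlation and 0.0163 by fry. With total-count scaling 3 members were higher and 2 lower, the list lost its call (camera adjusted p = 0.0932), and Ern1 was called higher, as it also was with upper-quartile factors, without a filter and without SKO replicate 3, with edgeR adjusted p-values of 0.00646, 0.0244, 0.0369 and 0.0252.

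Members of the carboxylesterase 1 family were among the largest falls. Ces1c (chromosome 8, 93099015 to 93131283) fell from 2891 ± 331 to 308 ± 57.1 CPM, a 9.38-fold decrease (log2 -3.23 ± 0.16, edgeR adjusted p = 3.73e-06). Ces1d fell from 1009 ± 101 to 119 ± 23.1 CPM, Ces1e from 309.5 ± 40.4 to 25.6 ± 3.20 CPM, Ces1f from 1041 ± 103 to 217 ± 35.7 CPM, and Ces1g from 82.4 ± 17.2 to 14.9 ± 4.63 CPM. These genes form a tandem family of similar sequence on chromosome 8, so the split of reads between its members is uncertain. Ces1c, Ces1d, Ces1e and Ces1f belong to the list of substrates of IRE1-dependent mRNA decay, in which all 17 members were called, 11 lower and 6 higher, with the same counts adjusted over the list alone. The other lower members included the lysosomal gene Hgsnat (log2 -1.44 ± 0.10), the cytochromes Cyp2e1 (log2 -1.29 ± 0.14) and Cyp1a2 (log2 -0.96 ± 0.13), Ergic3, Tapbp and Bloc1s1. Bloc1s1 stood at 1.26 ± 0.171 CPM in SKO and 0.367 ± 0.249 CPM in DKO. The higher members were Sparc, Galnt10, Scara3, Col6a1, Pdgfrb and Pmp22, with log2 fold changes from 0.58 (Pmp22) to 1.54 (Scara3). Sparc, Col6a1 and Pdgfrb are known as extracellular matrix or mesenchymal genes. The list's median was -0.96 (95% bootstrap interval -2.10 to 0.76). Its camera adjusted p was 1.44e-20, with adjusted p = 0.14 with an estimated correlation and 0.00414 by fry. Without SKO replicate 2 the higher calls dropped to 1, Sparc, and the lower to 10. Calls also ended for Bloc1s1 without any SKO library or DKO replicate 3, Scara3 without SKO replicate 3, Pdgfrb without SKO replicate 1, and Pmp22 without SKO replicate 3, DKO replicate 1 or DKO replicate 3 (edgeR adjusted p up to 0.148). Tapbp lost its call with total counts.

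**Figure D1:**
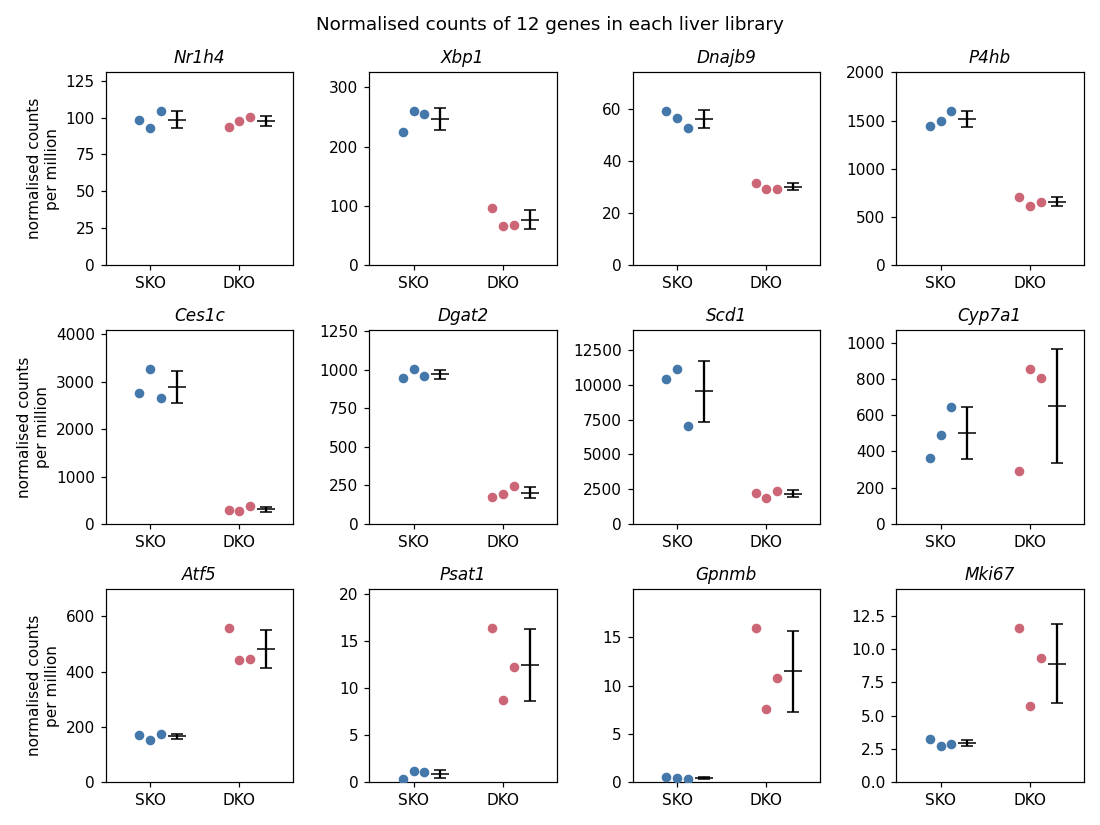
Normalised counts-per-million values (y axis, from 0) of 12 genes in the 3 SKO (blue) and 3 DKO (red) liver libraries, one point per library, with the mean and SD in black beside the points. Xbp1, Dnajb9, P4hb, Ces1c, Dgat2 and Scd1 lie lower and Atf5, Psat1, Gpnmb and Mki67 higher in each DKO library than in any SKO library, while Nr1h4 and Cyp7a1 overlap.

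Targets of ATF4 and CHOP, transcription factors of the integrated stress response, rose in part in DKO while Atf4 mRNA itself did not. Of 32 tested members, 17 rose and 1, Atf4, fell. The counts adjusted over the list alone were 23 higher and 1 lower. Atf5, a stress-induced transcription factor, rose from 166 ± 10.5 to 482 ± 67.0 CPM (log2 1.54 ± 0.11, edgeR adjusted p = 3.01e-05). The amino acid transporter subunit Slc3a2 rose from 48.7 ± 0.745 to 120.5 ± 17.3 CPM (log2 1.31 ± 0.10), and the serine synthesis gene Psat1 from 0.886 ± 0.443 to 12.4 ± 3.85 CPM (log2 3.78 ± 0.36). Asns, asparagine synthetase, rose from 6.51 ± 2.72 to 72.5 ± 5.48 CPM (log2 3.46 ± 0.26). Ddit3, which encodes CHOP, rose from 6.93 ± 1.57 to 15.7 ± 4.58 CPM (log2 1.18 ± 0.25, edgeR adjusted p = 0.0149). Atf4 fell from 105 ± 4.12 to 88.6 ± 3.32 CPM (log2 -0.25 ± 0.07, edgeR adjusted p = 0.0322), and its translation, which stress also controls, is not measured by these counts. The median log2 fold change was 0.95, with a camera adjusted p of 8.67e-16, adjusted p = 0.189 with an estimated correlation and 0.00965 by fry. Mean member levels, as log2(CPM + 1) relative to the mean of the 6 libraries, were 0.648 in DKO replicate 1 and 0.279 and 0.411 in the other DKO libraries. The call for Ddit3 ended without SKO replicate 1, SKO replicate 3 or DKO replicate 1 (edgeR adjusted p up to 0.0605), and that for Atf4 without any single library except SKO replicate 1 (up to 0.128) and under upper-quartile (log2 -0.18) or total-count scaling (log2 -0.02).

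Lipid synthesis genes fell in part in DKO. Of 24 genes of fatty acid and triglyceride synthesis, 12 fell and 1 rose. Dgat2, which catalyses the last step of triglyceride synthesis, fell from 971 ± 29.5 to 203.5 ± 38.3 CPM (log2 -2.25 ± 0.13, edgeR adjusted p = 1.34e-05). Scd1, the stearoyl-CoA desaturase, fell from 9541 ± 2168 to 2158 ± 249 CPM (log2 -2.15 ± 0.19), and Srebf1, which encodes the lipogenic factor SREBP-1, from 244 ± 31.0 to 87.9 ± 3.59 CPM (log2 -1.47 ± 0.10). Fasn, fatty acid synthase, fell by 0.48 ± 0.14 on the log2 scale (edgeR adjusted p = 0.0423). Of 25 genes of cholesterol synthesis and uptake, 10 fell and none rose, among them Insig1 (log2 -1.08 ± 0.10) and the sterol carrier Stard4 (log2 -0.98 ± 0.10). With p adjusted over the list alone, 14 lipid synthesis and 12 cholesterol genes were lower, and 1 of each was higher. Medians were -0.51 and -0.26, with camera adjusted p-values of 4.46e-13 and 7.65e-07, and adjusted p = 0.189 and 0.243 with an estimated correlation. By fry the adjusted p-values were 0.00965 and 0.0203. With total-count scaling, and without DKO replicate 2, there were 2 higher cholesterol genes, and 1 without SKO replicate 1, without a filter or with DESeq2. The call for Fasn ended without any single library except SKO replicate 3 (edgeR adjusted p up to 0.127), under upper-quartile and total-count scaling and with limma-voom, and no lipid synthesis gene was called higher by edgeR without SKO replicate 2, SKO replicate 3, DKO replicate 2 or DKO replicate 3.

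Few genes of fatty acid oxidation or glucose production changed. Of 25 genes of fatty acid oxidation and PPAR-alpha targets, 4 fell and none rose, among them Ppara itself (240 ± 3.35 to 152 ± 5.01 CPM, log2 -0.66 ± 0.07), the fatty acid binding protein gene Fabp1 (log2 -1.16 ± 0.13) and Acot1 (log2 -0.64 ± 0.15). The same number was lower when adjusted over the list alone. The median was -0.15 and turned to 0.07 with total counts, where 4 members were higher and 3 lower. The camera adjusted p was 0.0115, adjusted p = 0.551 with an estimated correlation, and without SKO replicate 1 the call ended (0.123, median -0.09). Fry did not call this list (adjusted p = 0.109). DESeq2 and the fit without a filter each called 8 members lower, 1 member was higher with DESeq2, with limma-voom and without SKO replicate 1 or DKO replicate 1, and Acot1 was not called without DKO replicate 1 or 3 or with total counts. Of 13 genes of gluconeogenesis and glycogen metabolism, Fbp1 (log2 0.49 ± 0.10) and Igfbp1 (log2 1.97 ± 0.41) rose and the glycogen synthase gene Gys2 fell (log2 -0.80 ± 0.16), as they did adjusted over the list alone. This list was not called (camera adjusted p = 0.997, and 0.999 with an estimated correlation), its median of -0.05 and mean of 0.16 had opposite signs, and camera gave the sign of the mean. Without DKO replicate 1 it was called higher (camera adjusted p = 0.000394, 4 members higher, median 0.19), and Igfbp1 lost its call without any library except DKO replicate 1 (edgeR adjusted p up to 0.115) and without a filter. The list's level, as mean log2(CPM + 1) relative to the 6 libraries, was -0.388 in DKO replicate 1 and 0.335 and 0.233 in the other DKO libraries.

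Cyp7a1 and Cyp8b1, main enzyme genes of bile acid synthesis, were not called. Cyp7a1, which encodes the rate-limiting cholesterol 7-alpha-hydroxylase, was 501 ± 142 CPM in SKO and 651 ± 312 CPM in DKO (log2 0.38 ± 0.48, edgeR adjusted p = 0.638). DKO replicate 1 stood at 291 CPM, below the SKO libraries (363 to 647), and DKO replicates 2 and 3 at 854 and 807, above them. Without DKO replicate 1 the log2 fold change of Cyp7a1 was 0.73 (edgeR adjusted p = 0.0901), without SKO replicate 3 it was 0.61, without SKO replicate 1 or DKO replicate 3 it was 0.19, and without DKO replicate 2 it was 0.13, so its level in DKO is left open. Cyp8b1, the sterol 12-alpha-hydroxylase gene, was 1109 ± 109 and 937 ± 121 CPM (log2 -0.24 ± 0.12, edgeR adjusted p = 0.195). Of 16 bile acid synthesis genes, 4 fell: the bile acid-CoA ligase gene Slc27a5 (1174 ± 36.8 to 534 ± 80.0 CPM, log2 -1.14 ± 0.12), Slc27a2 (log2 -0.53 ± 0.11), Akr1d1 (log2 -0.59 ± 0.14) and Amacr (log2 -0.26 ± 0.08). Cyp39a1, an oxysterol 7-alpha-hydroxylase gene, rose from 36.6 ± 6.52 to 68.7 ± 10.5 CPM (log2 0.91 ± 0.15, edgeR adjusted p = 0.00579). Of 18 genes of bile acid transport and FXR targets, 6 fell and 2 rose, Abcb1a (log2 0.59 ± 0.17) and Slco1a4 (log2 0.42 ± 0.13). The phospholipid transporter gene Abcb4 fell from 362 ± 18.0 to 240.5 ± 5.79 CPM (log2 -0.59 ± 0.08), the sterol transporter gene Abcg8 by 0.59 ± 0.10 on the log2 scale, and Nr0b2, which encodes the repressor SHP, from 13.5 ± 2.46 to 7.0 ± 0.404 CPM (log2 -0.95 ± 0.15). Slc10a1, the bile acid uptake transporter NTCP, fell by 0.47 ± 0.13 (edgeR adjusted p = 0.0259). The bile salt export pump gene Abcb11 was not called (407 ± 77.0 and 287 ± 51.5 CPM, log2 -0.50 ± 0.17, edgeR adjusted p = 0.0688), but was with DESeq2, without a filter and without SKO replicate 3.

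When each list was adjusted over the list alone, 5 synthesis genes were lower and 1 higher, and 10 transport genes lower and 3 higher. The 2 bile acid lists had medians of -0.25 and -0.30 and camera adjusted p-values of 0.0101 and 0.0327, and adjusted p = 0.468 and 0.317 with an estimated correlation. Fry did not call the synthesis list (adjusted p = 0.0707) and called the transport list (adjusted p = 0.0276). DKO replicate 1 had a relative level of -0.353 for the synthesis list, against 0.05 and -0.066 in the other DKO libraries. The synthesis list lost its call without DKO replicate 1 (camera adjusted p = 0.0929, median -0.14), and its lower members numbered 2 without SKO replicate 1 and 1 without SKO replicate 2, where Slc27a2 lost its call (edgeR adjusted p = 0.0527). The transport list lost its call without SKO replicate 2 (0.0614), SKO replicate 3 (0.0558) or DKO replicate 2 (0.122). Its rises fell to 0 without SKO replicate 1, DKO replicate 1 or DKO replicate 3 and to 1 without SKO replicate 2 or 3, with 3 falls without SKO replicate 2. With total counts 4 of its members were higher and 3 lower. Slc10a1 lost its call with total counts and without SKO replicate 2 or 3 (edgeR adjusted p up to 0.108). Calls ended for Akr1d1 without SKO replicate 1 or 2, for Amacr without any library except DKO replicate 2, for Abcb1a without any library, and for Slco1a4 without SKO replicate 1, SKO replicate 3, DKO replicate 1 or DKO replicate 3 (edgeR adjusted p up to 0.147 over these genes). Amacr was also not called with upper-quartile or total-count scaling, Abcb1a without a filter or with DESeq2, and Slco1a4 with RLE factors or limma-voom.

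Genes for proteins that hepatocytes secrete into plasma fell in part. Of 42 tested, 18 fell and 1, the fetuin gene Ahsg, rose (log2 0.65 ± 0.13). The protein C gene Proc fell from 525 ± 30.4 to 175 ± 17.4 CPM (log2 -1.58 ± 0.10, edgeR adjusted p = 1.51e-05), the complement C5 gene Hc from 893 ± 178 to 214 ± 25.2 CPM (log2 -2.06 ± 0.16), and the clotting factor gene F7 from 107 ± 10.6 to 49.1 ± 5.17 CPM (log2 -1.13 ± 0.10). Alb fell by 0.89 ± 0.19 on the log2 scale. With p adjusted over the list alone, 20 were lower and 3 higher. The median was -0.33, with a camera adjusted p of 1.73e-10, adjusted p = 0.254 with an estimated correlation and 0.0162 by fry. Without SKO replicate 2 only 10 members were lower and Alb was not called (edgeR adjusted p = 0.0503). Total counts gave 4 higher and 13 lower plasma protein genes with a median of -0.11, upper-quartile factors 3 higher and 16 lower, and DESeq2 and the fit without a filter 3 higher and 23 lower each. There were 2 higher with limma-voom and without SKO replicate 1 or DKO replicate 2. The acute phase list moved both ways. Itih4 (log2 -1.22 ± 0.16), the acute phase glycoprotein gene Orm1 (log2 -0.66 ± 0.13), the hepcidin gene Hamp (log2 -0.88 ± 0.20), Saa4 and Hp fell and Apcs rose (log2 0.85 ± 0.21) among 21 genes. When adjusted over the list alone, 5 were lower and 2 higher. It was not called (camera adjusted p = 0.721, 0.904 with an estimated correlation), with a median of 0.05 and a mean of 0.07 against a lower direction in camera, and the median was -0.09 without SKO replicate 1, -0.01 without SKO replicate 2, 0.28 without SKO replicate 3, 0.10 without DKO replicate 2 and -0.02 without DKO replicate 3. The acute phase calls were uneven: 6 higher and 2 lower with total counts, 5 higher and 3 lower without SKO replicate 3, and 2, 3 and 2 lower without SKO replicate 2, DKO replicate 1 and DKO replicate 3, with Hamp not called in these last cases (edgeR adjusted p up to 0.0899) and Orm1 not called with total counts. Saa4 lost its call without SKO replicate 2, SKO replicate 3 or DKO replicate 3, Apcs without any library except SKO replicate 3 or DKO replicate 2, and Hp without any except SKO replicate 1 (edgeR adjusted p up to 0.142). Saa4 and Hp were also not called with total counts, nor Hp with upper-quartile factors.

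Male-biased liver genes fell in part in DKO. Of 20 genes known to be higher in male liver, 10 fell and none rose, and 12 were lower adjusted over the list alone. Mup3, a major urinary protein gene, fell from 8083 ± 398 to 2347 ± 774 CPM (log2 -1.78 ± 0.24, edgeR adjusted p = 0.00156), the cytochrome gene Cyp2u1 from 15.2 ± 2.23 to 6.03 ± 0.416 CPM (log2 -1.34 ± 0.13), and Nudt7 from 962 ± 116 to 563 ± 103 CPM (log2 -0.77 ± 0.15). The Mup genes are near-identical copies, so reads that map to several of them may have been dropped or divided, and the level of each is uncertain. The median was -1.28, with a camera adjusted p of 3.47e-09, adjusted p = 0.269 with an estimated correlation and 0.0276 by fry. Relative levels of the male-biased list were -1.098 in DKO replicate 1 and -0.103 and -0.506 in DKO replicates 2 and 3, against 0.413 to 0.697 in SKO, and without DKO replicate 1 the lower members numbered 9. They numbered 6, 4, 3 and 4 without SKO replicate 1, 2 or 3 or DKO replicate 3. Of 12 female-biased genes, Cyp3a44 (0.428 ± 0.127 to 3.01 ± 1.56 CPM) and Sult2a1 rose and Acot3 fell (log2 -0.68 ± 0.13), with the same counts adjusted over the list alone. That list was not called (camera adjusted p = 0.0934, 0.512 with an estimated correlation, 0.109 by fry). It was called higher without a filter or without any one of SKO replicates 1 to 3 or DKO replicate 2, where camera adjusted p lay between 2.44e-05 and 0.0319, and its rises fell to 1 without any SKO library or DKO replicate 3.

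Among 22 genes of xenobiotic metabolism, Ces2a (log2 -1.44 ± 0.12), Ugt2b1 (log2 -0.87 ± 0.15) and Ces2c fell and Cyp3a11 (7866 ± 1405 to 12300 ± 790 CPM, log2 0.65 ± 0.16) and Aldh1a1 rose. When adjusted over the list alone, 5 were lower and 2 higher, and camera gave an adjusted p of 0.381, and 0.678 with an estimated correlation, with a lower direction against a mean of 0.03. Both rises lost their calls without SKO replicate 2, SKO replicate 3 or DKO replicate 3, Aldh1a1 also without DKO replicate 1 or 2, Ces2c lost its call without SKO replicate 2 or any DKO library and with total counts, and 7 members were higher with total counts. DESeq2 and the fit without a filter called 6 and 5 members lower. Of 18 hepatocyte transcription factor genes, Nr0b2, Nr5a2 (log2 -0.24 ± 0.07) and Foxa1 (log2 -0.40 ± 0.12) fell and 1 rose, with the same counts adjusted over the list alone. The camera adjusted p was 0.0949, and 0.317 with an estimated correlation, falling to 0.0397 without SKO replicate 2 and 0.0223 without a filter, and fry called the list lower (adjusted p = 0.0276). The median of -0.15 turned to 0.07 with total counts, and 1 member was lower under total-count or upper-quartile scaling and without any SKO library or DKO replicate 3, where neither Nr5a2 nor Foxa1 was called. Nr5a2 also lost its call without DKO replicate 1 or without a filter, and Foxa1 without DKO replicate 2 or with limma-voom (edgeR adjusted p up to 0.132), and no member was called higher without SKO replicate 3 or any DKO library.

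Most genes of the stellate cell and fibrosis list and of the macrophage list rose in DKO, and those of bile duct cells in part. Of 30 stellate cell and fibrosis genes, 21 rose and none fell. Most of those that rose were collagen and other matrix genes. The 9 not called were Acta2, Tagln, Lrat, Reln, Tgfb1, Tgfb2, Lox, Ctgf and Col5a1. Lum, which encodes the matrix proteoglycan lumican, rose from 9.13 ± 0.973 to 26.7 ± 5.29 CPM (log2 1.55 ± 0.15, edgeR adjusted p = 0.000225), Loxl1 from 1.61 ± 0.294 to 6.71 ± 2.42 CPM (log2 2.05 ± 0.28) and Col4a1 from 51.3 ± 4.55 to 109.6 ± 21.6 CPM (log2 1.10 ± 0.14). Col1a1, the main fibrillar collagen gene, rose from 9.24 ± 3.44 to 39.1 ± 18.5 CPM (log2 2.08 ± 0.46, edgeR adjusted p = 0.0379). Of 24 macrophage and monocyte genes, 16 rose and none fell, led by Gpnmb (0.429 ± 0.0858 to 11.5 ± 4.22 CPM, log2 4.73 ± 0.36), Mmp12 (2.51 ± 0.789 to 25.2 ± 8.55 CPM) and Trem2 (1.07 ± 0.340 to 6.44 ± 1.89 CPM). Marco, Adgre1, C1qa, C1qb and C1qc also rose. The 8 not called were Clec4f, Timd4, Cd5l, Vsig4, Csf1r, Ly6c2, Tyrobp and Mpeg1. DESeq2 called 21 of the 24 higher and the fit without a filter 22, so these missing calls do not set kinds of macrophage apart. Of 16 genes of cholangiocytes and progenitors, 7 rose, among them Spp1, which encodes osteopontin (55.7 ± 7.11 to 134 ± 36.5 CPM), Prom1 (log2 1.88 ± 0.35), Epcam (log2 1.24 ± 0.28) and Krt19 (log2 1.27 ± 0.31), and Krt23 fell (log2 -1.12 ± 0.28). Of 20 inflammatory chemokine and cytokine genes, 7 rose, including Icam1 (log2 0.88 ± 0.15), Tnfaip3 (log2 0.72 ± 0.14) and Cxcl14 (log2 2.08 ± 0.46), and none fell. Counts adjusted over the list alone were 24 stellate, 22 macrophage, 8 cholangiocyte and 7 inflammatory genes higher, and 1 cholangiocyte gene lower.

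Medians of these 4 lists were 1.09, 0.81, 1.10 and 0.17, with camera adjusted p-values of 1.16e-16, 1.44e-15, 0.000782 and 0.0327 in the order stellate, macrophage, cholangiocyte, inflammatory. They were adjusted p = 0.243, 0.243, 0.468 and 0.317 with an estimated correlation, and fry gave adjusted p = 0.0269, 0.0269, 0.109 and 0.0499, so it did not call the cholangiocyte list. The cholangiocyte median was 0.71 without DKO replicate 1, and the inflammatory median 0.30 without SKO replicate 1, 0.06 without SKO replicate 2, 0.28 without SKO replicate 3 and 0.02 without DKO replicate 3. DKO replicate 1 stood above the other DKO libraries, with relative levels of 0.808 for stellate genes (0.28 and 0.29 in the others), 0.768 for macrophages (0.174 and 0.478) and 0.668 for cholangiocytes (0.054 and 0.056). Without it, 19 stellate, 12 macrophage, 6 cholangiocyte and 4 inflammatory genes were higher. Without SKO replicate 2 these counts were 13, 10, 2 and 4, and without SKO replicate 3 the last 3 were 10, 2 and 4. The inflammatory list had 4 rises without DKO replicate 3 and lost its call there (camera adjusted p = 0.0936), without SKO replicate 2 (0.0694) and with total counts (0.134). Calls ended for Col1a1 without any SKO library or DKO replicate 2, and without a filter (edgeR adjusted p up to 0.132), for Krt23 without SKO replicate 2 or DKO replicate 3 (up to 0.0879), for Krt19 without SKO replicate 2, SKO replicate 3 or DKO replicate 1 (up to 0.0735) and for Epcam without SKO replicate 2 or 3 (up to 0.0619).

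Other cell types showed few calls. Among 15 endothelial genes only Vwf rose (log2 0.41 ± 0.12, edgeR adjusted p = 0.043), none adjusted over the list alone, and the camera adjusted p was 0.904, also with an estimated correlation. Their median was -0.003 (95% bootstrap interval -0.08 to 0.11). Of 14 lymphocyte genes, the immunoglobulin joining chain gene Jchain rose (log2 0.79 ± 0.23) and Ighm fell (log2 -1.56 ± 0.27), as they did adjusted over the list alone, with a camera adjusted p of 0.618 (0.864 with an estimated correlation). None of 4 neutrophil, 6 erythroid and 2 pancreatic genes tested was called by edgeR (1, 0 and 0 at an unadjusted p under 0.05), nor adjusted over the list alone, nor by DESeq2 or limma-voom. Values were Csf3r 2.65 ± 0.437 and 4.31 ± 1.70 CPM, S100a9 1.14 ± 0.440 and 1.42 ± 0.892, Alas2 188 ± 28.2 and 160 ± 27.4, Hbb-bs 139 ± 43.7 and 149.5 ± 24.3, Cela1 34.3 ± 5.66 and 25.2 ± 6.12, and Cela2a 0.537 ± 0.0824 and 0.715 ± 0.270, in SKO and DKO. The erythroid list had a camera adjusted p of 0.618, and 0.864 with an estimated correlation. Csf3r was called higher with total counts, without a filter and without DKO replicate 2, and Cela1 lower without a filter. With total counts 6 endothelial genes were higher. Vwf and Jchain lost their calls in DESeq2, Vwf without any library except SKO replicate 1 (edgeR adjusted p up to 0.153) and Jchain without any except DKO replicate 2 (up to 0.143).

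Genes of cell division, the p53 response and glutathione metabolism rose in part. Of 28 cell cycle genes, 16 were higher and none lower, among them the proliferation marker Mki67 (2.95 ± 0.259 to 8.89 ± 2.97 CPM, log2 1.59 ± 0.26) and the cyclin genes Ccnb2 (log2 1.74 ± 0.26) and Ccna2 (log2 1.80 ± 0.29). Of 22 p53 and apoptosis genes, 8 rose and none fell, led by the p53 targets Eda2r (1.04 ± 0.312 to 6.72 ± 1.09 CPM, log2 2.70 ± 0.25, edgeR adjusted p = 0.000121), Phlda3 (log2 2.64 ± 0.32) and the death receptor gene Tnfrsf10b (log2 2.57 ± 0.39). Of 20 NRF2 and glutathione genes, 9 rose and none fell, including the epoxide hydrolase gene Ephx1 (609 ± 81.6 to 1087 ± 52.3 CPM, log2 0.84 ± 0.12), the quinone reductase gene Nqo1 (log2 0.87 ± 0.15) and Gsta1 (log2 2.23 ± 0.36), whose family has close copies. The counts adjusted over the list alone were 20, 8 and 9 higher. Medians were 0.85, 0.37 and 0.50, and camera adjusted p-values 6.48e-08, 9.05e-05 and 8.5e-06, with adjusted p = 0.282, 0.243 and 0.347 with an estimated correlation. By fry the adjusted p-values were 0.0226, 0.0203 and 0.0484. The p53 median was 0.12 without DKO replicate 1 and the NRF2 median 0.31 without SKO replicate 3, and 1 NRF2 gene was lower without DKO replicate 1. DKO replicate 1 had the highest relative level in each (0.513, 0.428 and 0.669), with the other DKO libraries at 0.149 and 0.226, 0.174 and 0.233, and 0.066 and 0.379. Cell cycle rises numbered 9, 10 and 10 without SKO replicate 2, SKO replicate 3 and DKO replicate 1, and with total counts 13 p53 genes were higher.

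Clock genes fell in part. Of 18 circadian clock genes, 8 fell and 1, Npas2, rose from 0.180 ± 0.119 to 0.689 ± 0.108 CPM. Tef (log2 -0.53 ± 0.10) and Hlf (log2 -0.50 ± 0.10) were among those that fell. With p adjusted over the list alone, 10 were lower and 2 higher. The median was -0.41, with a camera adjusted p of 0.00256, adjusted p = 0.189 with an estimated correlation and 0.00982 by fry. The clock list had 4 higher and 3 lower members with total counts, 5 lower with upper-quartile factors and 4 lower without SKO replicate 2, and the time of day of sampling is not given in the sources used here. Npas2 lost its call without SKO replicate 2 or 3 and with DESeq2, and its log2 fold change went from 1.94 to 2.57 without SKO replicate 1. Of 13 immediate early genes, Atf3 (1.04 ± 0.302 to 7.40 ± 3.40 CPM) and Klf6 (log2 0.995 ± 0.198) rose, also adjusted over the list alone. Fry did not call that list (adjusted p = 0.177), and its camera adjusted p was 0.0785 (0.563 with an estimated correlation). The camera adjusted p was 0.000385 without SKO replicate 2, where Klf6 lost its call (edgeR adjusted p = 0.0508), 0.0103 without DKO replicate 2 and 0.0285 without a filter.

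Of 22 nuclear genes of the mitochondrial respiratory chain, 4 fell, among them Uqcrb (log2 -0.38 ± 0.08), Ndufb8 (log2 -0.30 ± 0.07) and Atp5o (log2 -0.28 ± 0.09), and 3 were lower adjusted over the list alone. The camera adjusted p was 0.0327, and adjusted p = 0.625 with an estimated correlation. That call ended without SKO replicate 1 (0.101), SKO replicate 2 (0.0559) or DKO replicate 1 (0.119, median -0.10), with 2 lower members in the last 2 cases, when Ndufb8 was not called, and under upper-quartile (0.0553) or total-count scaling (0.251), and fry did not call the list (adjusted p = 0.112). Atp5o lost its call without any library except SKO replicate 1, and with upper-quartile factors, a minimum of 1 CPM in 3 libraries, DESeq2 or limma-voom. With total counts the median turned from -0.16 to 0.05, with 5 members higher and none lower. None of 22 cytosolic ribosomal protein genes was called by edgeR (4 at an unadjusted p under 0.05), by DESeq2 or by limma-voom, nor adjusted over the list alone (Rpl4 log2 0.09 ± 0.09, Rps3 log2 0.07 ± 0.08; camera adjusted p = 0.313, 0.641 with an estimated correlation), but fry called the list higher (adjusted p = 0.0478), and 14 were higher with total counts, 3 with upper-quartile factors and 1 without a filter or without SKO replicate 1. All 37 genes of the mitochondrial genome had 0 counts in every library.

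**Figure D2:**
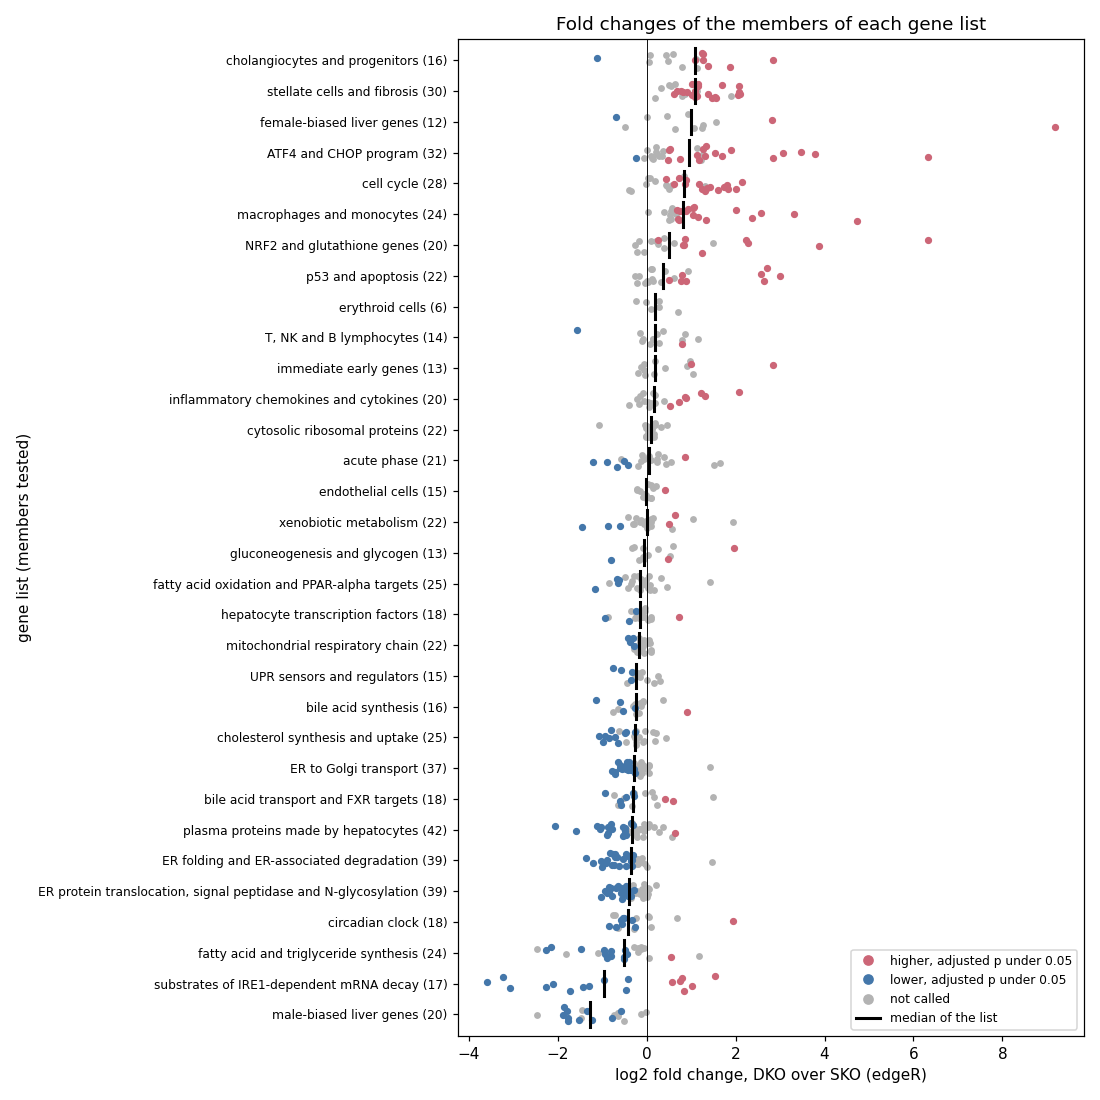
Log2 fold changes, DKO over SKO, by edgeR (x axis) of the tested members of each gene list (y axis), one point per gene with random vertical offset, red for higher, blue for lower and grey for not called, with a black bar at each list's median. Medians run from -1.28 for male-biased liver genes to 1.10 for cholangiocytes and progenitors.

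The largest rises were from SKO levels near the limit of detection. Sult2a1, a sulfotransferase gene known to act on bile acids and steroids, had 2 counts over the SKO libraries and 1730 over the DKO libraries, a ratio of normalised counts of 704 (95% counting interval 195 to 5818). Sult2a2 had 3 and 1533 counts, a ratio of 416 (142 to 2019), and the cystine transporter gene Slc7a11 had 3 and 347, a ratio of 94.2 (32.0 to 459). Sult2a5 and Vmn2r3 had no counts in SKO and 172 and 184 in DKO, so they were at least 46.7-fold and 49.9-fold higher, taking 3 counts over the group as the limit. The Sult2a genes form a cluster of similar sequence on chromosome 7, so the share of each copy is uncertain. Next came Gldn (0.0800 ± 0.0696 to 4.49 ± 2.85 CPM), Sprr1a (0.192 ± 0.179 to 9.29 ± 5.95 CPM) and Ly6d (0.957 ± 0.221 to 44.0 ± 37.5 CPM). The largest falls outside the Ces1 family were Cnmd (4.34 ± 0.862 to 0.332 ± 0.0855 CPM, log2 -3.69 ± 0.30), Clec2h (log2 -2.39 ± 0.38) and Gabbr2 (46.4 ± 1.89 to 9.29 ± 2.5 CPM, log2 -2.33 ± 0.17). Calls ended for Sult2a1, Sult2a2, Slc7a11 and Ly6d without any SKO library or DKO replicate 3, and for Sult2a5 in these cases and without DKO replicate 1 (edgeR adjusted p up to 0.208 over these 5 genes). Sult2a1, Slc7a11 and Ly6d were not called without a filter, nor Ly6d with limma-voom. The sizes of several of these rises depend on single libraries. All SKO counts of Sult2a1 and Sult2a2 were in SKO replicate 1, and Slc7a11 stood at 10.9 CPM in DKO replicate 1 against 0.978 and 3.53 in the other DKO libraries. Without SKO replicate 1 the log2 fold changes of Sult2a1, Sult2a2 and Slc7a11 went from 9.18, 8.50 and 6.33 to 12.03, 11.86 and 7.25, and without DKO replicate 1 to 8.45, 7.91 and 5.11. The values of 12.03 and 11.86 compare with no SKO counts, so they are set by how the fit treats 0 and are not measured folds. Without DKO replicate 1 those of Gldn, Sprr1a and Ly6d went from 5.76, 5.55 and 5.53 to 5.08, 4.89 and 4.61, while Gldn was 5.16 without SKO replicate 2 and Sprr1a 6.62 without SKO replicate 3.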

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

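All alternatives were fixed before the data were examined, and no test in this part was chosen after the result was seen. With total counts as the only scaling, 4397 genes were called, 3859 higher and 538 lower, of which 975 rose and 107 fell at least 2-fold. TMM factors were higher in each DKO library than in any SKO library, and leaving them out raised the median gene by 0.22 on the log2 scale in DKO. RLE factors, upper-quartile factors, a different or no filter, DESeq2 and limma-voom kept the total of calls within 1.5 times of 2803, with 2419 of the same genes called by DESeq2 and 2506 by limma-voom. Leaving out 1 library at a time gave 1419 to 2739 genes, 674 to 1569 higher and 745 to 1200 lower, and 483 to 915 changed at least 2-fold, 332 to 724 higher and 141 to 191 lower; the lowest counts were those without SKO replicate 2, except the lowest of falls of at least 2-fold, which was without SKO replicate 3. Fewer samples tend to reduce the number of calls, but not every count fell. Without DKO replicate 2, 1569 genes were higher against 1446 with all libraries, and 915 changed at least 2-fold against 751. No list held with an estimated correlation (0 of 32 by camera, with 6 at an unadjusted p under 0.05), against 20 by fry. Camera with an estimated correlation is weak with so few degrees of freedom, as given with the processing. No paired analysis was possible because the labels tie no library of one group to one of the other.

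Of 109 called genes that were chosen by the rule given with the processing, 84 were called in each of the 6 fits without 1 library and 25 were not in at least 1. The 31 called genes named after their values were seen are counted apart, with 8 called in each of these fits and 23 not in at least 1. None of either set changed sign without 1 library. Signs turned only among genes that were not called: Nr1h4 had a log2 fold change of 0.04 with upper-quartile factors, 0.20 with total counts and -0.07 to 0.03 without 1 library (0.03 without SKO replicate 3, 0.01 without DKO replicate 1), S100a9 of -0.34 to 0.68 without 1 library (-0.34 without DKO replicate 1), and Hbb-bs of -0.12 to 0.31 (-0.12 without SKO replicate 3, -0.03 without DKO replicate 1). The cause was not tested. At this depth, genes under about 1 CPM, such as the Sult2a genes in SKO, have folds limited by counting error.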

Other observations

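The tests of a lower hepatocyte share, of DKO replicate 1 alone, of RNA from female animals and of other splits of the libraries were chosen after the results were seen. Among called genes that belong to none of the lists and had at least 10 CPM on average, the thyroxine-binding globulin gene Serpina7 rose from 78.8 ± 14 to 480.1 ± 55.3 CPM (log2 2.61 ± 0.15, n = 3 per group, edgeR adjusted p = 1.34e-05), and Retreg3, an ER-phagy receptor gene, fell from 136 ± 6.20 to 29.0 ± 3.16 CPM (log2 -2.23 ± 0.09, edgeR adjusted p = 1.18e-06). Both were called in each fit without 1 library. Cyp2a4, a cytochrome gene with close copies, rose from 37.4 ± 24.8 to 330 ± 121 CPM (log2 3.14 ± 0.64, edgeR adjusted p = 0.0356) and the microtubule-associated exchange factor gene Arhgef2 from 6.05 ± 0.425 to 28.5 ± 13.1 CPM (log2 2.24 ± 0.37, edgeR adjusted p = 0.0128). Calls ended for Cyp2a4 without any library except SKO replicate 3 (edgeR adjusted p up to 0.117; log2 3.81 without SKO replicate 3) or without a filter, and for Arhgef2 without SKO replicate 1 or 2 (up to 0.0611). The others by this rule, Sult2a2, Ly6d, Ces1g and Gabbr2, are described above.

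Most genes of the stellate cell and fibrosis list and of the macrophage list, and 7 of 16 of cholangiocytes and progenitors, rose in DKO. A lower share of hepatocytes alone would raise the markers of every other cell type alike, if levels per cell were unchanged. The endothelial list had a median log2 fold change of -0.003 (95% bootstrap interval -0.08 to 0.11). Medians were 0.19 (-0.08 to 0.58) for lymphocytes and 0.2 (-0.12 to 0.49) for erythroid cells, against the stellate list's 1.09 (0.84 to 1.31). A rise of that size was thus not seen in those lists. Levels per cell are not measured, so a lower share of hepatocytes is not excluded. A rise in DKO replicate 1 alone is argued against by the fit without it. There the 69 members tested, called or not, had a median of 0.76, against 1.03 with all libraries. The 95% bootstrap interval of 0.59 to 0.92 resamples member genes, which move together, and holds no spread between libraries. Relative levels of the stellate, macrophage and cholangiocyte lists in DKO replicates 2 and 3 also lay above those in each SKO library. Open remain more cells of these types, or more transcript per cell, which bulk counts cannot separate, and any unlabelled difference in preparation between the groups. A fibrotic response in DKO liver is therefore a hypothesis only, to be checked by histology.

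Of 20 male-biased genes, 10 fell in DKO. RNA from female animals is argued against by Xist, at most 0.342 CPM in DKO. Shuffling of reads between near-identical copies is argued against as the whole cause by the 7 members without close copies. Their median was -0.74 (95% bootstrap interval -1.34 to -0.58, over members and without the spread between libraries). However, only C8b, Nudt7 and Cyp2u1 among them were called by edgeR (adjusted p = 0.0389, 0.00652 and 0.000199). C8b was not called without SKO replicate 2, SKO replicate 3, DKO replicate 1 or DKO replicate 2 (edgeR adjusted p up to 0.119) or with total counts. No biological explanation of this fall was tested. DKO replicate 1 had the lowest level.

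The IRE1 decay list split in direction. Reads moved between Ces1 copies are argued against by their sum over 8 genes, which fell from 5471 ± 559.5 to 714.5 ± 124.5 CPM, log2 -2.94. Its 6 higher members (median 0.81) were picked because they rose, so their size decides nothing, and whether they followed a rise of stellate cell transcripts stays open. Increased mRNA decay by IRE1 in hepatocytes without XBP1 is a hypothesis for the Ces1 fall, to be checked by mRNA half-lives, and lower transcription stays open, since counts do not measure decay.

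Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes called by edgeR (2803, highest other 0), as many changed at least 2-fold (751, highest other 0) and as many lists called by camera with the preset correlation (22, highest other 21). The splits are too few for a share under 0.05, the smallest being 0.1. Each other split mixes SKO and DKO libraries in both groups, so the genotype difference enters the residual spread. Its count of 0 genes called therefore does not measure false calls.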
